A study of Syzygium samarangense with 6 samples.

How the data were processed

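Poly(A) RNA from the pulp of wax apple fruit on day 5 after harvest was sequenced as paired-end reads in 6 libraries, 3 from control fruit and 3 from fruit treated with 800 µM melatonin. Per the labels, the 3 libraries of a group are biological repeats, so the p-values here measure the spread between those repeats. No reference genome was used here: all features are unigenes of the authors' own assembly, whose identifiers have the format of Trinity, in a version not given in the sources used here.

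Per the submitters' processing notes, reads were trimmed with cutadapt, checked with FastQC, quantified with Salmon and tested with edgeR, in versions not given in the sources used here. The authors deposited estimated counts per unigene, which need not be whole numbers, and between 5.44% and 6.58% of the values in a library were not whole. The authors also deposited TPM values, rounded, in 2 tables that differed in 0 values. The authors' table gave a log2 fold change of melatonin over control with a p-value and an adjusted p for each unigene. The authors' read statistics, per the file headers, were counts of raw and trimmed reads and the percent GC of each library. The authors' annotation listed an Nr hit (the protein database of NCBI), a SwissProt hit, GO terms and KEGG pathways, each with the name of its source organism where there was one.

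The table held 46137 unigenes with a median length of 468 bases, from 201 to 15308. An Nr hit was listed for 27348, a SwissProt hit for 20117 and any protein description for 28154, while 25588 carried a GO or KEGG term. Unigenes are not whole genes: fragments of 1 gene, alleles and near-identical paralogs can stand as separate unigenes, and Salmon splits the reads they share, so levels of such families are uncertain. Descriptions name the closest database protein, not an established gene of wax apple.

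The Nr column named only green plants, and the planned rule on Nr organisms (fungal, bacterial or animal genera) therefore assigned 0 unigenes. Of the 4029 unigenes whose Nr hit was cork oak (*Quercus suber*), 3112 had a SwissProt hit and 86.0% of those hits were fungal, against 1.42% among hits of *Eucalyptus grandis*. Classes were therefore set after the data had been seen. A unigene with an Nr hit in a genus of the Myrtales, the order of wax apple and eucalyptus, is called a wax apple unigene here. The others were assigned by the organism of their SwissProt hit to animal, fungus, virus, prokaryote or protist, other plant or ribosomal DNA, and those with only a cork oak hit or with no hit were kept as classes of their own. Such a class describes the annotation and does not identify a species.

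Estimated counts were rounded to whole numbers. Unigenes were filtered with filterByExpr of edgeR 4.0.16, scaled by TMM and tested with edgeR's robust quasi-likelihood fit, two-sided, in R 4.3.3, with Benjamini-Hochberg adjustment over all tested unigenes and an adjusted p under 0.05 as the threshold, with no limit on fold change. CPM values are TMM-scaled, SD values are over the 3 libraries of a group, and fold changes are log2 of melatonin over control with a standard error (SE). The SE was derived from the quasi-likelihood test, as the absolute log2 change over the square root of its F statistic. Ratios against groups with few counts carry an exact 95% interval of the pooled counts. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The 16735 wax apple unigenes tested were also counted among these calls. In a refit of wax apple unigenes alone, with its own filter, 16696 were tested. Levels of virus unigenes and of insect stage markers are CPM of the library total, without TMM.

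A total of 31 gene lists was fixed by words in the protein descriptions: ROS-scavenging enzymes, glutathione S-transferases, class III peroxidases, thioredoxins and glutaredoxins, NADPH oxidases, pectin-degrading enzymes, expansins with xyloglucan endotransglucosylases and endoglucanases, cell wall synthesis, phenylpropanoid and lignin enzymes, flavonoid enzymes, ethylene, abscisic acid, jasmonate, auxin response, mitochondrial respiration, glycolysis and TCA cycle, fermentation, sucrose and starch metabolism, GABA shunt, melatonin synthesis, heat shock proteins, pathogenesis-related proteins, disease resistance receptors, WRKY and NAC transcription factors, phospholipases and lipases, photosynthesis, ribosomal proteins, and markers of the cuticle (epidermis), vascular tissue and seed. Lists with 3 or more tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Terms with 10 to 500 tested members were tested with one-sided Fisher's exact tests for each direction against the tested unigenes that carried a term. Shares of counts were compared by exact two-sided permutation tests, for which 3 against 3 libraries give a smallest p of 0.1. The lists, the tests, the rule for named genes and the first group of other settings below were chosen before the data were examined.

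The rule named, in each direction, the 6 called unigenes with the largest fold change among those with a protein description, a mean of at least 5 CPM and no overlap between the groups. It added, for each list with 3 or more called members, the most abundant called member in each direction. For ROS-scavenging enzymes, glutathione S-transferases, ethylene, pectin-degrading enzymes, phenylpropanoid and flavonoid enzymes and melatonin synthesis it also added the 2 most abundant members, whatever their test. Other unigenes named were chosen after their values were seen.

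The quasi-likelihood test was tested on simulated counts with 200 changed unigenes. The spread of those counts was taken from the control libraries alone. Melatonin libraries correlated less with each other (Pearson r 0.896 to 0.953) than controls did (0.972 to 0.980), so the rates below need not hold for these data. Over 23535 unigenes the quasi-likelihood test recovered 50% of changes of 1 on the log2 scale and 78% of changes of 2, with 12.3% of its calls false. Over 16584 wax apple unigenes fitted alone it recovered 69% and 93%, with 9% of calls false. DESeq2 1.42.0 recovered 61% and 86% over all unigenes with 28.6% of calls false, and limma on log2(TPM + 1) recovered 81% and 100% over 34690 unigenes with 2.2% false. For limma the simulated values had the same spread for all unigenes, so its rates cannot be set against those of the other tests.

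Other settings, chosen beforehand, were DESeq2 size factors, no filter and a mean of at least 5 CPM as filters, leaving out each library, the replicate number as a block, leaving out unigenes by SwissProt organism, summing unigenes with 1 description, DESeq2, limma-trend on log2(TPM + 1) for unigenes with a TPM of at least 1 in 3 libraries, pseudocounts of 0.1 and 5, an adjusted p under 0.01, a fold limit, and other term sizes and backgrounds. The refit of wax apple unigenes, leaving out the classes of other organisms, edgeR's exact test and the class from SwissProt were added after the data had been seen. Python 3.11.15 with scipy 1.17.1 was used for preparation, and figures were drawn with matplotlib 3.10.9.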

Results

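RNA was profiled in the pulp of wax apple (*Syzygium samarangense*), a tropical Myrtaceae fruit, on day 5 after harvest. Melatonin is an indole compound that plants make from tryptophan and that is applied to harvested fruit; here 3 libraries came from fruit treated with 800 µM melatonin and 3 from control fruit. Total estimated counts were 24154567, 20865773 and 22070913 in control libraries 1, 2 and 3 and 21441900, 22128803 and 23782066 in melatonin libraries 1, 2 and 3. They stood for 81.61% to 83.6% of the read pairs of a library. Between 37594 and 39065 unigenes had a count in 5 of the libraries, against 44434 in melatonin library 3. The title of the study names the question, whether melatonin slows decay of the fruit by way of its antioxidant capacity.

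Over all 24184 tested unigenes, those called between melatonin and control fruit were mostly annotated to insects and other animals (196), fungi (136), no protein (133) or wax apple (104). Smaller classes were other plants (12), only a cork oak hit (8), prokaryotes or protists (7) and a virus (1). The insect ones were nearly absent from control pulp. Glyceraldehyde-3-phosphate dehydrogenase of a fly type, a glycolytic enzyme, stood at 0.0158 ± 0.0274 CPM in control and 73.2 ± 80.7 CPM in melatonin libraries (SD, n = 3), a ratio of 5063 (95% interval 908 to 200027) against 1 count in all control libraries. Among wax apple genes, a unigene of omega-hydroxypalmitate O-feruloyl transferase, which feruloylates suberin, fell from 128 ± 69.9 to 13.1 ± 5.33 CPM. A more abundant unigene of that transferase, not called, had 405 CPM in control and 255 CPM in melatonin libraries. Inorganic pyrophosphatase 2, which hydrolyses pyrophosphate, fell from 70.7 ± 13.6 to 11.5 ± 1.28 CPM. Callose synthase 11, which makes a wall glucan, rose from 28.3 ± 2.41 to 47.1 ± 1.79 CPM, and the cytokinin and purine carrier purine permease 1 rose from 19.6 ± 3.49 to 57.1 ± 1.99 CPM.

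In edgeR's quasi-likelihood test 374 unigenes were higher and 223 lower in melatonin fruit at an adjusted p under 0.05, and 3757 had an unadjusted p under 0.05. By annotation, the calls held 193 higher and 3 lower animal unigenes, 70 higher and 66 lower fungal ones, 69 higher and 35 lower wax apple ones, and 27 higher and 106 lower with no hit. Animal unigenes were 565 and wax apple unigenes 16735 of those tested. The groups did not overlap for 5697 of the tested unigenes, or 23.6%, where chance gives 10%. DESeq2 called 1057 higher and 778 lower, and limma on log2(TPM + 1) called 674 and 689. Without control library 1, 2 or 3 or melatonin library 2, edgeR called 0, 1, 0 and 0 unigenes, with 3676, 3984, 3634 and 4031 at an unadjusted p under 0.05. Without melatonin library 1 it called 435 higher and 59 lower, and without melatonin library 3 410 and 537.

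**Figure D1:**
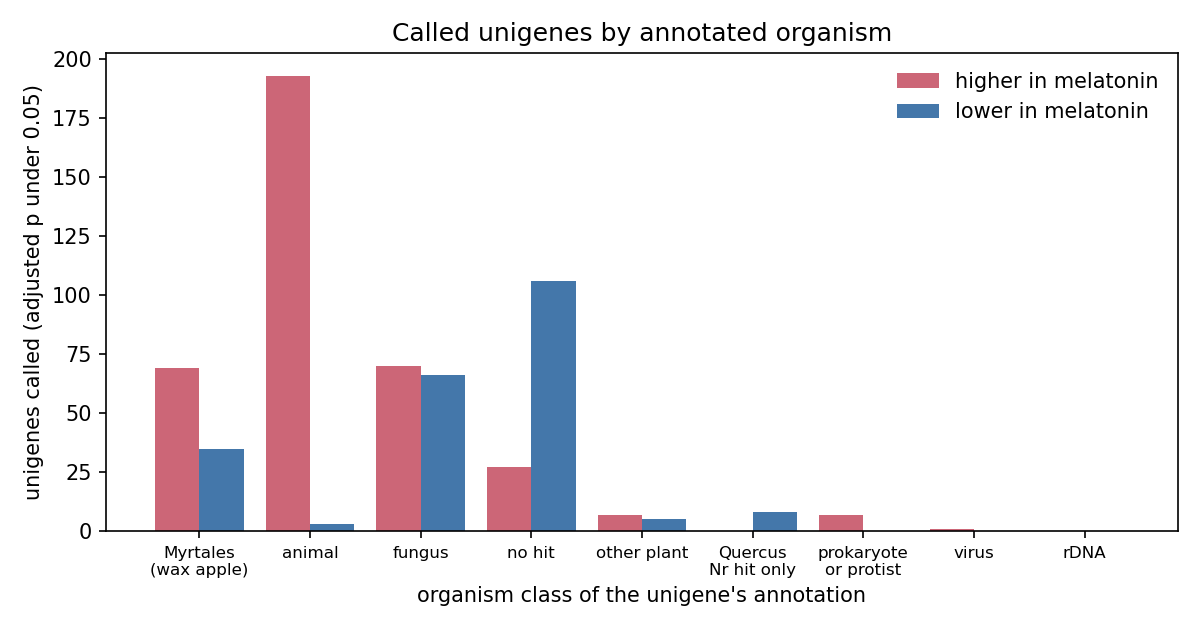
Number of unigenes called higher (red) and lower (blue) in melatonin libraries, adjusted p under 0.05 in edgeR's quasi-likelihood test, by the organism class of the annotation. Animal-annotated unigenes made up 193 of the 374 higher calls, and unigenes with no hit 106 of the 223 lower ones.

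The wax apple calls named by the rule included 5 single unigenes. That of the feruloyl transferase of the suberin branch had a log2 change of -3.29 (SE 0.52, adjusted p = 0.044). A unigene of transcription factor MYB39, a regulator of suberin genes, fell from 42.2 ± 16.1 to 5.02 ± 2.64 CPM (n = 3, log2 change -3.07, SE 0.51, adjusted p = 0.046). Inorganic pyrophosphatase 2 fell by 2.62 (SE 0.18, adjusted p = 0.016), and NRT1/PTR FAMILY 5.3, a carrier of the nitrate and peptide transporter family, fell by 2.45 (SE 0.41, adjusted p = 0.046). Callose synthase 11 rose by 0.74 (SE 0.11, adjusted p = 0.042).

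Fitted alone, 16696 wax apple unigenes gave 3 higher and 3 lower calls in edgeR's quasi-likelihood test and 2154 at an unadjusted p under 0.05, 1135 of them higher. Apart from the pyrophosphatase, whose adjusted p was 0.029 in this fit, the calls were named after their values were seen and each had an adjusted p of 0.046. Fold changes here are those of this fit, and CPM values are scaled over all unigenes. Scopoletin glucosyltransferase, which glucosylates the defence coumarin scopoletin, rose from 8.48 ± 1.57 to 39.9 ± 4.93 CPM (n = 3, log2 change 2.23, SE 0.18). Cytochrome P450 714A1, of a family that inactivates gibberellins, rose from 5.45 ± 0.925 to 22.9 ± 3.47 CPM (log2 change 2.07, SE 0.19), and purine permease 1 rose by 1.54 (SE 0.15). WRKY transcription factor 28 fell from 3.45 ± 0.0826 to 0.255 ± 0.0836 CPM (log2 change -3.74, SE 0.32), and a protein of unknown function, EUGRSUZ_G02080, from 3.24 ± 1.08 to 0.0871 ± 0.0393 CPM (log2 change -5.11, SE 0.47).

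The counts behind these wax apple calls moved with the fit. With the p-values of the fit over all unigenes adjusted over wax apple unigenes alone, edgeR called 0 of the 104 that passed among all unigenes, with 2035 at an unadjusted p under 0.05. Fitted alone, DESeq2 called 274 higher and 238 lower, edgeR's exact test 174 and 134, and limma on log2(TPM + 1) 3 and 1. Without control libraries 1, 2 or 3 or melatonin libraries 1 or 2, the wax apple fit gave 0, 1, 0, 0 and 0 calls, at 1341, 1848, 1343, 1860 and 2000 unadjusted. Without melatonin library 3 it gave 73 higher and 136 lower, with all 6 of the calls kept. All 6 were also kept in DESeq2, in edgeR's exact test, with no filter and with DESeq2 size factors. Only 2 were kept with the stricter filter, 3 in limma on log2(TPM + 1) and 4 with unigenes summed by description. Over all settings the adjusted p of scopoletin glucosyltransferase reached 0.81 at the highest.

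**Figure D2:**
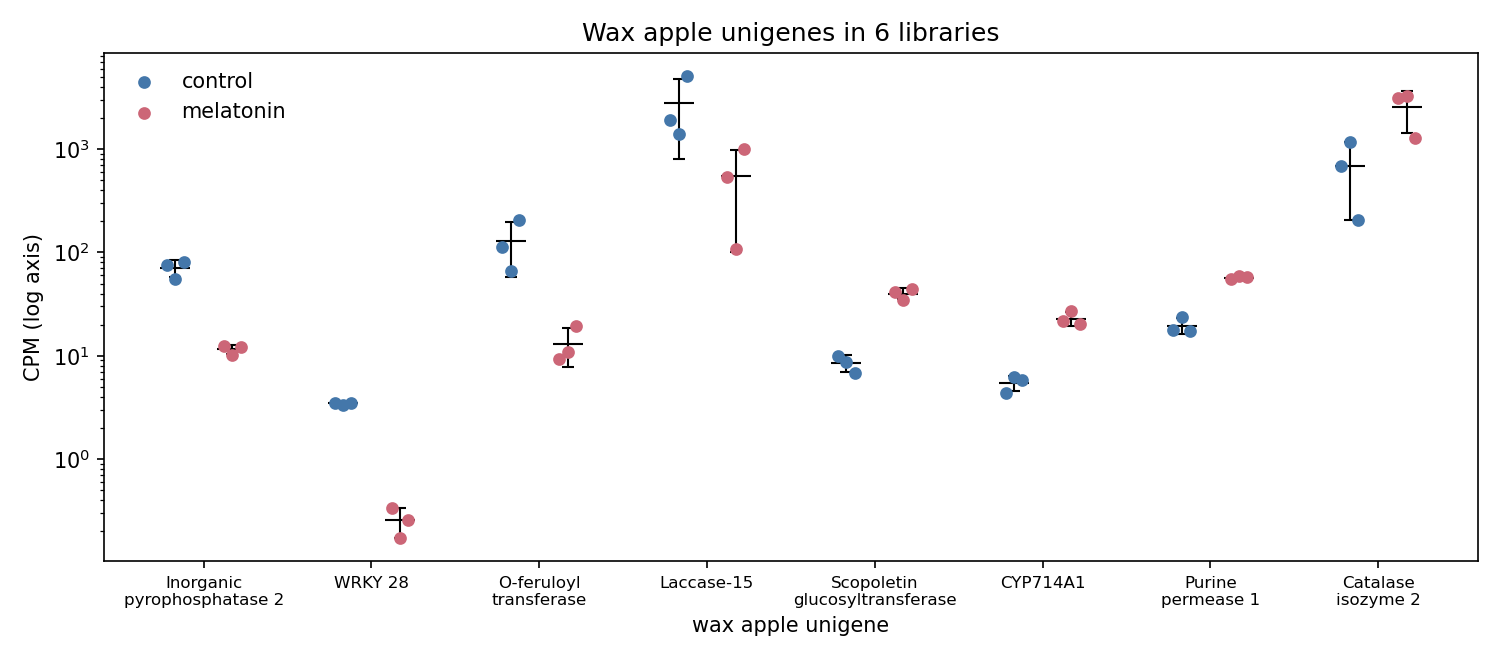
CPM (log axis) of 8 wax apple unigenes in 3 control (blue) and 3 melatonin (red) libraries, 1 point per library, with the group mean and SD as bars. The groups do not overlap for any of the 8, while laccase-15 and catalase isozyme 2 did not pass the test (adjusted p = 0.30 and 0.27).

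Of the ROS-scavenging enzymes, the most abundant by their mean over all 6 libraries were catalases. Catalase isozyme 2, which breaks down hydrogen peroxide, had 688 ± 484 CPM in control and 2564 ± 1120 in melatonin fruit (n = 3, log2 change 1.90, SE 0.70, adjusted p = 0.27 in edgeR). Another catalase unigene had 309 ± 241 and 861 ± 361 CPM (log2 change 1.48, SE 0.74, adjusted p = 0.41). The identifiers of these catalase unigenes differ only in the last number, so both may come from 1 gene. DESeq2 called catalase isozyme 2 at an adjusted p of 0.012, and over all settings its adjusted p ran from 0.012 to 0.46. Of 55 ROS-scavenging enzymes tested, edgeR called 0 higher and 1 lower, a fungal superoxide dismutase (log2 change -6.21), and 5 and 3 when adjusted over the list alone. Of the 36 wax apple members 0 were called, 0 also when adjusted over the list alone, and 2 were higher and 4 lower at an unadjusted p under 0.05. Glutathione S-transferases, which conjugate toxic compounds to glutathione, held 1 called member of 45, of a fly type (log2 change 8.09), with 4 higher and 1 lower when adjusted over the list alone. The most abundant wax apple members had 425 ± 38.6 and 328 ± 92.4 CPM (log2 change -0.37, SE 0.22, adjusted p = 0.47) and, for parC, a log2 change of -0.10 (SE 0.22, adjusted p = 0.87). Thioredoxins and glutaredoxins held 1 call among 70, a yeast glutaredoxin-2 that was lower (log2 change -5.53), also 1 when adjusted over the list alone. The 3 NADPH oxidases held 0, with 1 at an unadjusted p under 0.05. In camera, adjusted p values of these lists were 0.94, 0.85, 0.52 and 0.94 over all unigenes.

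Class III peroxidases, which oxidise phenols in the wall, were lower as a group among wax apple unigenes (17 tested, median log2 change -0.24, camera adjusted p = 0.043), against an adjusted p = 1.0 with an estimated correlation. Peroxidase 24 fell from 24.9 ± 8.16 to 6.3 ± 1.02 CPM (log2 change -1.98, SE 0.29, adjusted p = 0.042 over all unigenes), and adjusted over the list alone 1 member was higher and 2 lower. This group call was lost without control library 2 or 3 or melatonin library 1 or 2 (adjusted p = 0.14, 0.34, 0.12 and 0.71). It was also lost with no filter (adjusted p = 0.089), with unigenes summed by description (0.073) and in limma on log2(TPM + 1) (0.13). Phenylpropanoid and lignin enzymes were lower as a group over all unigenes (67 tested, median -0.30, camera adjusted p = 0.0031; adjusted p = 0.96 with an estimated correlation). Among 63 wax apple members the adjusted p was 0.0014, against adjusted p = 1.0 with an estimated correlation. Of these members 0 were called by edgeR, also when adjusted over the list alone, and at an unadjusted p under 0.05 1 was higher and 11 lower. Laccase-15, of the oxidases that couple monolignols, had 2801 ± 2002 and 545 ± 443 CPM (log2 change -2.36, SE 0.92, adjusted p = 0.30). Cinnamyl alcohol dehydrogenase 2, which reduces monolignol aldehydes, had 1250 ± 285 and 691 ± 193 CPM (log2 change -0.86, SE 0.27, adjusted p = 0.20). Its adjusted p was 0.03 in DESeq2, the lowest over the settings, and 0.40 at the highest. Without melatonin library 2 the group's adjusted p was 0.14 over all unigenes and 0.088 among wax apple ones. Flavonoid enzymes held 1 call among 31, also when adjusted over the list alone, with a camera adjusted p of 0.94. This was a unigene described as flavonoid 3',5'-hydroxylase, of the blue pigment branch, chosen after its values were seen. It rose from 70 ± 10.4 to 131 ± 16.9 CPM (log2 change 0.90, SE 0.15, adjusted p = 0.043). A called unigene whose identifier differs only in the last number was described as 4-hydroxyphenylacetaldehyde oxime monooxygenase (log2 change 0.88), so the enzyme behind the description is uncertain. A flavonoid 3-O-glucosyltransferase and dihydroflavonol 4-reductase had log2 changes of -0.04 (SE 0.19) and -0.06 (SE 0.26), with adjusted p values of 0.95 and 0.93.

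Among wax apple unigenes, photosynthesis genes were higher as a group in the pulp of melatonin fruit (36 members, median log2 change 0.73, camera adjusted p = 6.0e-08). With an estimated correlation camera gave an adjusted p of 1.0. In another split of the libraries these members reached a camera adjusted p of 3.8e-20. No member was called (0 in edgeR, also when adjusted over the list alone), while 15 were higher and 0 lower at an unadjusted p under 0.05. Chlorophyll a-b binding protein 151 of the light-harvesting antenna, chosen after its values were seen, had 145 ± 61.3 and 318 ± 111 CPM (n = 3, log2 change 1.13, SE 0.40, adjusted p = 0.25; 0.033 in DESeq2). Over all unigenes the list had 103 tested members and did not pass (camera adjusted p = 0.11). Of these, 0 were animal and 0 fungal, so the members left out of the wax apple group were of neither class. Mitochondrial respiration was lower among 57 wax apple members (median -0.13, camera adjusted p = 0.0015; adjusted p = 1.0 with an estimated correlation), with 0 called in edgeR and 7 lower at an unadjusted p under 0.05. The call was lost without control library 2 or melatonin library 2 (adjusted p = 0.13 and 0.062). Over all unigenes this list had 24 higher and 6 lower members of 171, 53 and 21 when adjusted over the list alone, and a camera adjusted p of 0.66. Of its tested members 54 were animal and 34 fungal. Insect cytochrome c oxidase subunit 1 rose from 0.128 ± 0.0812 to 187 ± 168 CPM, and a fungal ATP synthase subunit J fell by 6.70 on the log2 scale. Disease resistance receptors, which recognise pathogen effectors, were higher among 363 wax apple members (median 0.12, camera adjusted p = 0.04; adjusted p = 1.0 with an estimated correlation). Without control library 2 or melatonin library 2 the adjusted p was 0.87 and 0.81. The called members were At1g12280 and At1g50180 types (log2 changes 1.43 and 2.11; 0 when adjusted over the list alone).

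**Figure D3:**
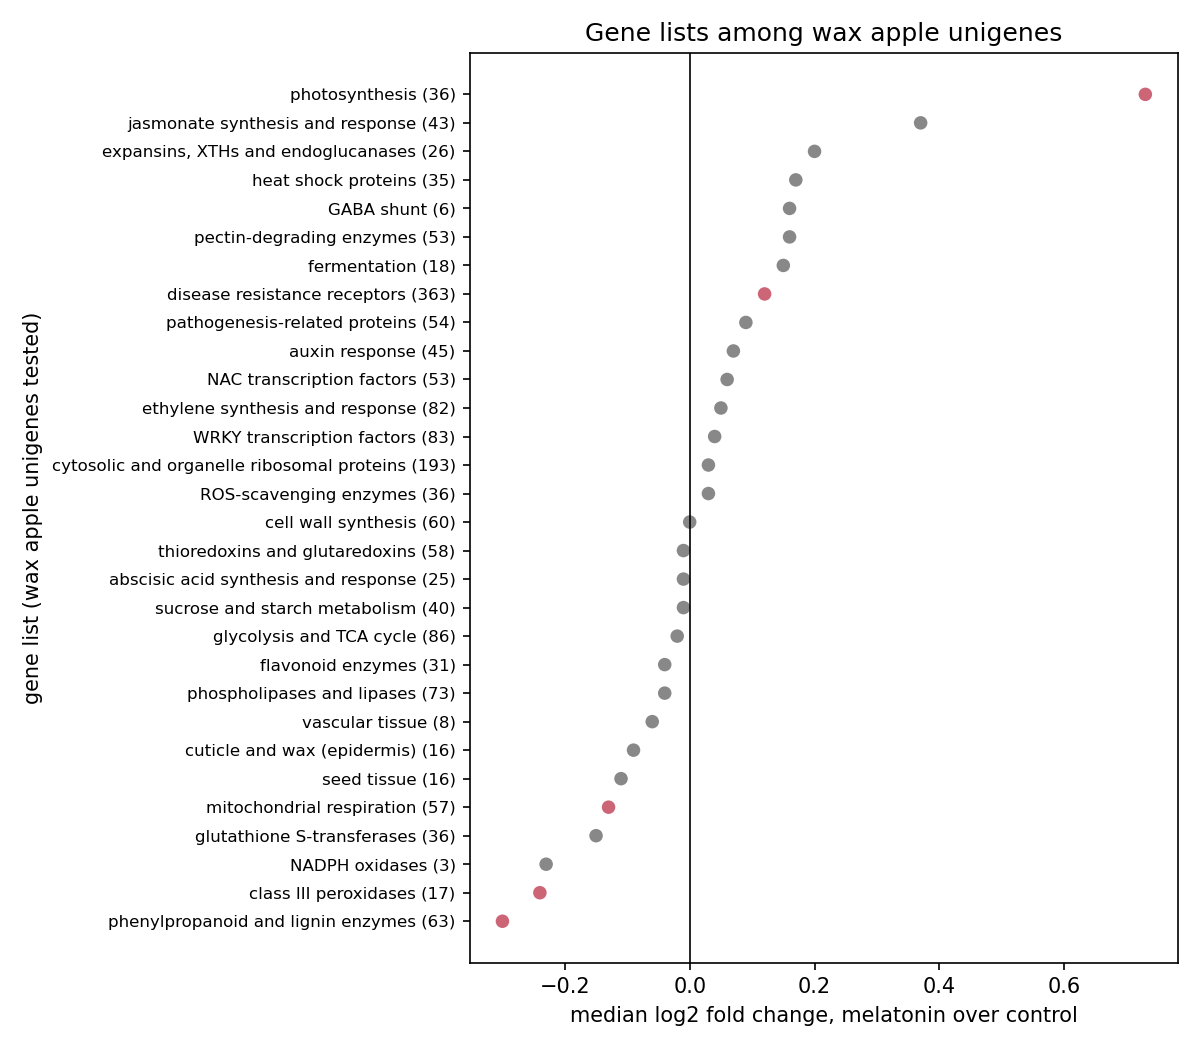
Median log2 fold change (melatonin over control) of each gene list among wax apple unigenes, with the number of members tested in brackets; red points passed camera at a preset correlation, none passed with an estimated one. The medians run from -0.30 for phenylpropanoid and lignin enzymes to 0.73 for photosynthesis.

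Of 51 auxin response genes 7 were called higher and 0 lower, 6 of the 7 from wax apple, and 8 higher when adjusted over the list alone. Their camera adjusted p was 0.19 over all unigenes and 0.10 among 45 wax apple members, of which 7 were higher and 0 lower when adjusted over the list alone. Auxin response factor 1, which binds auxin-inducible promoters, rose from 30.5 ± 2.04 to 47.5 ± 1.77 CPM (log2 change 0.64, SE 0.10, adjusted p = 0.042). The Aux/IAA repressors AUX28, IAA9 and IAA17, chosen after their values were seen, rose by 2.28, 1.23 and 1.21 on the log2 scale (SE 0.31, 0.16 and 0.22). Cell wall synthesis held 3 higher and 0 lower calls among 66 members, also when adjusted over the list alone, with a camera adjusted p of 0.94. They were callose synthase 11, callose synthase 8 (log2 change 1.48) and cellulose synthase 3 (log2 change 0.94, and -0.05 when unigenes of 1 description were summed). WRKY transcription factors held 0 higher and 2 lower calls among 84, also when adjusted over the list alone, at a camera adjusted p of 0.56. They were WRKY28 and WRKY71 (log2 change -5.45), unigenes whose identifiers differ only in the last number, so both may come from 1 gene. Among the 53 NAC factors, edgeR called 0, with 5 higher and 3 lower at an unadjusted p under 0.05 and a camera adjusted p of 0.94.

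For ethylene (90 members), abscisic acid (26) and jasmonate (48) the calls were 0 in edgeR, also when adjusted over the list alone, and camera adjusted p values were 0.94. The counts of wax apple members at an unadjusted p under 0.05 were 12 for ethylene, 0 for abscisic acid and 8 for jasmonate. The ethylene-forming 1-aminocyclopropane-1-carboxylate oxidase had 897 ± 330 and 611 ± 466 CPM (log2 change -0.55, SE 0.66, adjusted p = 0.73). The ethylene-response factor RAP2-2 had 595 ± 47.5 and 613 ± 74.8 CPM (log2 change 0.04, SE 0.15, adjusted p = 0.91). Pectin-degrading enzymes, which soften the wall, gave 0 calls among 62 members (5 wax apple members unadjusted, camera adjusted p = 0.56). Beta-galactosidase had 1465 ± 166 and 1555 ± 428 CPM (log2 change 0.09, SE 0.25, adjusted p = 0.90), and a polygalacturonase beta subunit had 404 ± 284 and 514 ± 534 CPM (log2 change 0.35, SE 0.89, adjusted p = 0.88). Expansins, xyloglucan endotransglucosylases and endoglucanases gave 0 among 31 (3 unadjusted, 0.94), sucrose and starch enzymes 0 among 41 (5 unadjusted, 0.94) and the GABA shunt 0 among 8 (0 unadjusted, 0.94). Serotonin N-acetyltransferase 1, the 1 member of the melatonin synthesis list, had 6.87 ± 1.24 CPM in control and 5.93 ± 0.336 CPM in melatonin fruit (log2 change -0.21, SE 0.19, adjusted p = 0.63). Over all unigenes the median and the camera direction had opposite signs for NADPH oxidases, pectin-degrading enzymes, expansins, ethylene, abscisic acid, jasmonate, pathogenesis-related proteins, WRKY and NAC factors and mitochondrial respiration.

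The lists described next, other than cuticle, vascular tissue and seed, had most or all of their called members from other organisms. Ribosomal proteins, the building blocks of ribosomes, were higher as a list (565 tested, 103 higher and 13 lower, 136 and 44 when adjusted over the list alone, camera adjusted p = 3.9e-04; adjusted p = 0.96 with an estimated correlation). Of the tested members 86 were animal and 186 fungal, and the 193 wax apple members, of which 1 was called higher, had an adjusted p of 0.40. The called one, 60S protein L12-A, had 0 CPM in control and 1.04 ± 0.0562 CPM in melatonin libraries. Whether it is a gene of the fruit was not tested. Without melatonin library 3 the list had an adjusted p of 0.091. Insect 60S protein L7a rose from 0.105 ± 0.0133 to 67.9 ± 62.5 CPM, and fungal S30-A fell from 9.74 ± 6.48 to 0.144 ± 0.134 CPM. Glycolysis and the TCA cycle had 20 higher and 3 lower calls among 169 (29 and 10 when adjusted over the list alone, camera adjusted p = 0.33), with a fungal ATP-citrate synthase that fell by 4.95. Fermentation had 5 higher and 3 lower among 33 (6 and 5 when adjusted over the list alone, 0.85). The higher ones were an insect alcohol dehydrogenase (log2 change 7.79), a pair of yeast alcohol dehydrogenases 2 and a pair of yeast pyruvate decarboxylases, while those that fell included a mould alcohol dehydrogenase 1 (-4.68). Heat shock proteins had 3 higher, all insect, and 1 lower, fungal, among 62 (7 and 2 when adjusted over the list alone, 0.11). The chaperone Hsc70-4 stood at 0.157 ± 0.0666 and 144 ± 140 CPM and fungal Hsp70 at 3.35 ± 2.88 and 0.0751 ± 0.0289 CPM. Pathogenesis-related proteins had 2 higher calls among 64, both chitinase-like proteins of flies (4 higher and 2 lower when adjusted over the list alone, 0.94). Phospholipases and lipases had 1 higher call among 77, an animal lipase (log2 change 7.44; 1 when adjusted over the list alone, 0.40). The cuticle list held 2 lower wax apple calls among 16, a unigene of the feruloyl transferase and 3-ketoacyl-CoA synthase 20, which elongates fatty acids (log2 change -4.32; 2 when adjusted over the list alone, 0.32). Markers of vascular tissue (9 members) and seed (16) had 0 calls in edgeR and camera adjusted p values of 0.27 and 0.40, with 1 and 2 wax apple members at an unadjusted p under 0.05.

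GO and KEGG terms among the called unigenes followed the same division: 65 of 1254 terms were enriched among higher and 6 among lower unigenes by Fisher's exact test. Ribosome (68 of 146 members called higher, adjusted p = 5.3e-74), sleep (6 of 11) and oogenesis (5 of 12) were among the terms of the higher unigenes, as were yeast-form cell wall (7 of 19) and auxin-activated signaling (8 of 76, adjusted p = 0.0059). In a background of wax apple unigenes, an alternative added after the data had been seen, 8 terms were enriched among the 69 higher and 0 among the 35 lower, for which 21 had an unadjusted p under 0.05. Auxin-activated signaling (7 of 70, adjusted p = 3.7e-05) and plant hormone signal transduction (9 of 180, adjusted p = 6.7e-05) came first, followed by amino acid transmembrane transporter activity (4 of 37, adjusted p = 0.011) and oligopeptide transport (4 of 39, adjusted p = 0.011). The term amino acid transmembrane transport did not pass (3 of 34, adjusted p = 0.084). With the calls of DESeq2 on wax apple unigenes 10 terms were enriched among higher and 6 among lower, with edgeR's exact test 6 and 3, and without melatonin library 3 1 and 4. Auxin-activated signaling was among those of the higher unigenes in each. Over all unigenes 0 terms were enriched without control library 1, 2 or 3 or melatonin library 2, where 0, 1, 0 and 0 unigenes were called. Without melatonin library 1 they were 108 higher and 0 lower, and without melatonin library 3 the lower terms were 14.

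Unigenes annotated to other organisms took different shares of the libraries. Animal unigenes held 0.143%, 0.138% and 0.118% of counts in control and 0.317%, 2.49% and 0.998% in melatonin libraries, means of 0.133% ± 0.0134 and 1.27% ± 1.11 (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Within them the insect share was higher in each melatonin library (0.152%, 1.95% and 0.582%) than the control mean of 0.00365% ± 0.000486 (n = 3, exact permutation p = 0.1). Of 1898 animal unigenes, 275, 300 and 260 had a count in control libraries and 1547, 1730 and 1829 in melatonin libraries. The difference in animal share, 1.14 percentage points, was 0.525 without melatonin library 2. Of the 193 animal unigenes called higher, 108 had a *Drosophila* protein as their closest SwissProt entry.

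Fungal unigenes held 0.41%, 0.319% and 0.153% of counts in control libraries, 0.0729% and 0.0674% in melatonin libraries 1 and 2 and 2.36% in melatonin library 3 (means 0.294% ± 0.131 and 0.832% ± 1.32, exact permutation p = 1.0). The difference of 0.538 percentage points was -0.224 without melatonin library 3. Calls of budding yeast unigenes were 68 higher and 17 lower of 185 tested, and those of other fungi 2 higher and 49 lower of 393. The budding yeast share was 0.0217% and 0.0166% in melatonin libraries 1 and 2, below each control (0.0675%, 0.0603% and 0.0278%), and 0.48% in melatonin library 3. Other fungi held 0.0513%, 0.0508% and 1.88% in melatonin libraries against 0.343%, 0.259% and 0.125% in controls, and the exact permutation p was 1.0 for both shares. An uncharacterised protein closest to YEL023C of *Saccharomyces* fell by 6.16 (SE 0.52, adjusted p = 0.03), and a protein with only a cork oak hit, LOC112000929, fell from 23.2 ± 20.7 to 0.174 ± 0.143 CPM (n = 3, adjusted p = 0.048). Wax apple unigenes held 86% ± 1.96 and 83.9% ± 1.85 of counts (exact permutation p = 0.2). By SwissProt organism alone, animals held 3.2% ± 0.151 and 4.41% ± 1.16 (p = 0.1), fungi 2.59% ± 0.614 and 2.62% ± 0.724 (p = 0.9) and bacteria 0.144% ± 0.00901 and 0.143% ± 0.00639 (p = 1.0) in exact permutation tests.

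**Figure D4:**
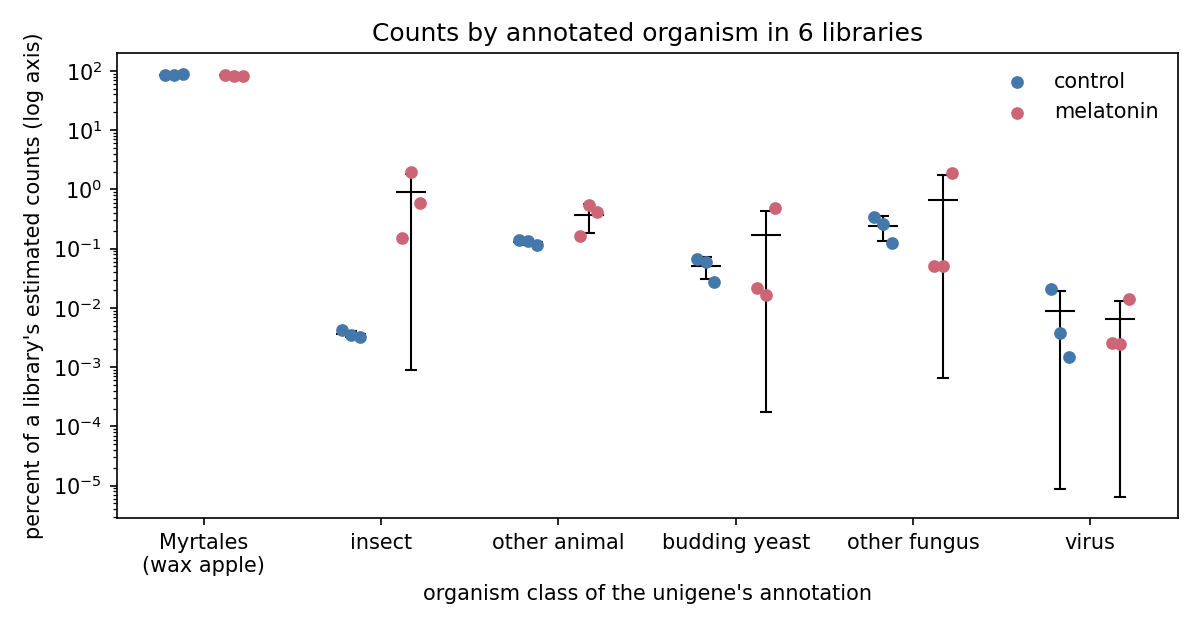
Percent of each library's estimated counts (log axis) in unigenes of 6 organism classes, 1 point per library, control in blue and melatonin in red, with the mean and SD as bars. Insect unigenes held 0.152%, 1.95% and 0.582% in melatonin libraries against a control mean of 0.00365%, and both fungal classes were highest in melatonin library 3.

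Over all tested unigenes, libraries of 1 group correlated better (mean Pearson r across unigenes 0.950) than libraries of different groups (0.865), a gap of 0.085. Among wax apple unigenes alone the gap was 0.009. The first principal component over all unigenes carried 63.3% of the variance, with controls at -93.3, -96.5 and -95.3 and melatonin libraries at 69.2, 140.7 and 75.3. Among wax apple unigenes it carried 47.1%, with controls at -25.4, -15.6 and -32.8, melatonin libraries 1 and 2 at 34.7 and 75.2, and melatonin library 3 at -36.1, beyond the controls.

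The authors' deposited table called 1102 unigenes higher and 588 lower. Of its calls 679 higher and 12 lower were animal, 65 and 190 fungal, and 137 and 140 wax apple unigenes in the authors' deposited table. Of the 1690 calls in the authors' deposited table, 1364 were tested here. Called here were 462 (27.3% of the 1690), all in the same direction, and these were 77.4% of the calls made here. The authors' calls held no small fold changes, while calls here had no limit on fold change. Both percentages therefore compare calls made with unlike filters and thresholds. For wax apple, 64 of the 277 calls in the authors' deposited table were called here over all unigenes, and the 6 calls of the wax apple fit were all among them.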

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

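The tests on insect and fungal unigenes in this part were chosen after the results were seen, and those on the shared adjustment and the shared spread were written down before their values were computed.

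An uncharacterised mimivirus-type protein, R707, had too few counts for the test and so stands outside the comparisons, but its mean was above each control, by melatonin library 3 alone. That mean was 0.645 CPM, from 0, 0 and 1.93 in melatonin libraries 1, 2 and 3, against 0.0828, 0.0479 and 0 in controls. The other 3 virus-annotated unigenes were tested, and edgeR called 1 higher. This was a genome polyprotein closest to maize rayado fino virus, with 21, 19.5 and 15.2 CPM in melatonin libraries and 6.67, 7.57 and 6.43 in controls (log2 change 1.40, SE 0.18, adjusted p = 0.042). A replicase closest to beet necrotic yellow vein virus had 0.513, 0.271 and 116 CPM in melatonin libraries and 0.538, 1.05 and 0.272 in controls (adjusted p = 0.35). A replicase polyprotein closest to Ononis yellow mosaic virus had 4.2, 4.52 and 8.96 CPM in melatonin libraries and 202, 29.4 and 8.2 in controls (adjusted p = 0.23).

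Animal-annotated unigenes were higher in melatonin libraries, with 193 called. Among the called insect ones were 47 different ribosomal proteins, which is consistent with RNA of an insect in the melatonin samples. Over all 565 tested animal unigenes the median control level was 0% of the melatonin level, which argues against wax apple genes with chance matches to animal proteins for most of the set. Unigenes of animals other than insects held 0.129% of control counts against 0.376%, so some of these may still be genes of the fruit. Whether the melatonin treatment itself led to this stays open, since the exact permutation p of the animal share, 0.1, is the smallest that 3 against 3 libraries allow, and fruit with and without insects may have fallen into the groups by chance.

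Fungus-annotated unigenes took 2.36% of the counts of melatonin library 3, more than of any other library. Over 398 fungal unigenes the levels in that library had a Spearman rho of -0.01 with the control mean, which argues against the same fungi as in the mean of the controls. With control libraries 1, 2 and 3 its rho was 0.17, -0.10 and -0.17, but control library 1 also had only 0.41 and 0.36 with control libraries 2 and 3, which had 0.96 with each other. Its rho was 0.65 with melatonin library 1 and 0.56 with melatonin library 2, and control library 1 had 0.52 and 0.58 with melatonin libraries 1 and 2. Whether the melatonin treatment itself shaped the fungi stays open, with an exact permutation p of 1.0 for the fungal share.

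Of the 104 wax apple unigenes called among all unigenes, only 6 were called when wax apple unigenes were fitted alone. With the p-values of the fit over all unigenes adjusted over wax apple unigenes alone, 0 were called, which is consistent with a Benjamini-Hochberg adjustment shared with unigenes of other organisms, whose many small p-values raise the p that passes. At the p of 0.0012 that passed among all unigenes, the wax apple fit held 126 unigenes against 104, which argues against shared spread estimates as the reason. Which of the 104, the 6 included, respond to melatonin stays open.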

How the results depend on the processing

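Among the settings compared here, those of wax apple unigenes fitted or adjusted alone, the exact test, the classes from SwissProt and leaving out the classes of other organisms were chosen after results were seen. With 3 libraries a group and animal and fungal shares that differ by library, the counts of calls were not stable. DESeq2 called 595 of the 597 unigenes again. The groups did not overlap for any of the 597, so leaving out 1 library could not turn a direction. Tests of named genes kept their side of the threshold in 664 comparisons with a setting, no longer passed in 405, newly passed in 4 (3 in DESeq2, 1 with the block) and reversed in 4. The 664 include named genes that were not called here, such as the catalases, for which staying means again not passing. Only genes called here could add to the 405, so the 664 overstate how often a call was kept. Counts and shares moved in 139 comparisons and were the same in 86. Those 86 include shares by the Nr organism, which were 0 in each library and could not move. Tests of single lists stayed in 73 and were lost in 31. The cause was not tested unless stated. Depth limits ratios for unigenes nearly absent from a group: the fly dehydrogenase had 1 count in all control libraries.

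Counts are given as higher and lower, with 374 and 223 unigenes called in the report, 69 and 35 of them wax apple, and 3 and 3 in the wax apple fit. DESeq2 called 1057 and 778 unigenes, 335 and 293 of them wax apple, and 274 and 238 in the wax apple fit. The exact test called 958 and 631, 199 and 149 of them wax apple, and 174 and 134 in the wax apple fit. Limma on log2(TPM + 1) called 674 and 689, with 73 lower wax apple unigenes, and 1 lower in the wax apple fit. A pseudocount of 0.1 gave 980 and 866 with 80 lower wax apple unigenes, and one of 5 gave 142 and 142, 32 and 21 of them wax apple. No filter gave 0 and 0 in edgeR, 0 and 0 of them wax apple, with 6751 at an unadjusted p under 0.05, and 7 higher in the wax apple fit. The stricter filter gave 1 and 2, 0 and 1 of them wax apple, with 2020 unadjusted, and 1 and 1 in the wax apple fit; here fewer unigenes were tested. Without SwissProt hits in fungi, bacteria or animals there were 64 and 68, 30 and 8 of them wax apple, and without the classes of other organisms 14 and 28, 13 and 6 of them wax apple. Fitted alone, wax apple unigenes gave 3 and 3, adjusted alone 0 and 0, and summed by protein description 5 and 5. An adjusted p under 0.01 left 0 and 0 unigenes in edgeR, and 0 and 0 wax apple ones, against 3757 at an unadjusted p under 0.05. DESeq2 size factors, a fold limit, summing over all unigenes and other term sizes and backgrounds kept counts within 1.5 times.

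Leaving out 1 library gave from 0 to 435 higher and 0 to 537 lower unigenes, from 0 to 130 and 0 to 213 wax apple ones among all, and from 0 to 73 and 0 to 136 in the wax apple fit. The same settings gave from 1 to 3 higher and 0 to 4 lower lists, from 1 to 2 and 0 to 6 among wax apple unigenes, and from 0 to 108 and 0 to 14 terms.

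The replicate number as a block gave 627 higher unigenes, 77 lower wax apple ones among all and 1 lower in the wax apple fit. That wax apple fit kept 1 of the 6 calls made without the block. With the block, lists were 2 higher and 2 lower over all unigenes and 1 higher among wax apple ones, where disease resistance receptors had an adjusted p of 0.058, and catalase isozyme 2 had an adjusted p of 0.037. The labels do not state that the numbers pair the libraries. Same-numbered libraries had correlations of their deviations of -0.163, -0.016 and -0.233, and over all unigenes no library correlated best with the library of its own number. Among wax apple unigenes only control and melatonin library 2 did, at 0.105. Deviations from the mean of 3 libraries are tied to each other, so these correlations cannot exclude a pairing.

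Over all unigenes 1 list was called higher and 1 lower, and 2 and 3 among wax apple unigenes. With the stricter filter lists were 3 and 2, without the classes of other organisms 3 and 4, with a pseudocount of 5 3 higher, and without SwissProt hits in other organisms 0 higher. With an estimated correlation 0 and 0 lists passed over all and 0 and 0 among wax apple unigenes, as with fry (0 and 0, and 0 and 0). Terms were 65 and 6, with the calls of DESeq2 103 and 19, and 8 and 0 with calls and background of wax apple unigenes. By the Nr organism the differences in share were 0; by SwissProt organism they were 0.0306 percentage points for fungi, -0.000532 for bacteria and 1.21 for animals, and with the class from SwissProt where Nr is not Myrtales 0.538 for fungi and 1.14 for animals. The gap in correlation of 0.085 was 1.250 over the 1000 most variable unigenes and 0.009 among wax apple unigenes.

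Summing unigenes by protein description, which pools organisms, reversed the fold change of LOC112000929 (0.88), mould alcohol dehydrogenase 1 (2.08), S30-A (0.77) and cellulose synthase 3 (-0.05).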

Other observations

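The tests of the cytokinin group and of insect stages, and the splits for wax apple terms, were chosen after the results were seen, as were the genes named in the next 2 paragraphs. The suberin list was written after the calls were seen, and its test was set down before it was run.

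Cytokinin signalling genes stood among the higher wax apple calls of the fit over all unigenes. A unigene of response regulator ARR9, a primary cytokinin response gene, rose from 4.09 ± 1.02 to 12.2 ± 2.65 CPM (n = 3, log2 change 1.58, SE 0.26, adjusted p = 0.042 in edgeR). Response regulator ARR6 rose from 10.6 ± 0.892 to 18.2 ± 0.758 CPM, and the cytokinin receptor histidine kinase 2 from 21.6 ± 1.98 to 36.8 ± 3.71 CPM, each with an adjusted p of 0.042 in edgeR. In the wax apple fit these 3 were not called, and the term for cytokinin signalling did not pass among the higher wax apple calls (3 of 30 members, adjusted p = 0.064). Another ARR9 unigene, not called in either fit, had 10.3 CPM in control and 10.6 CPM in melatonin fruit (log2 change 0.04 in the wax apple fit).

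Other single wax apple genes, in none of the fixed lists, were called over all unigenes. NRT1/PTR FAMILY 4.3 rose from 6.04 ± 2.14 to 40.9 ± 14.6 CPM (n = 3, log2 change 2.76, SE 0.36, adjusted p = 0.042 in edgeR), and the efflux carrier DETOXIFICATION 56 from 17.5 ± 3.51 to 57.8 ± 8.23 CPM (adjusted p = 0.037). The reductoisomerase of the plastid isoprenoid pathway rose from 51.2 ± 2.18 to 101 ± 7.06 CPM (log2 change 0.98, adjusted p = 0.036). The senescence-type cysteine protease SAG39 rose from 0.897 ± 0.31 to 13.2 ± 7.77 CPM (log2 change 3.88, SE 0.57). The ubiquitin ligase XERICO, linked to abscisic acid levels, fell from 113 ± 5.68 to 61.7 ± 1.39 CPM (log2 change -0.87, SE 0.09, adjusted p = 0.036). Not called was the small chain of ribulose bisphosphate carboxylase, a member of the photosynthesis list, with 42 ± 12.4 and 111 ± 74.3 CPM (log2 change 1.40, SE 0.57, adjusted p = 0.32).

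A hypothesis drawn from the calls was that the whole cytokinin response group may have shifted in melatonin fruit. Of 30 tested wax apple members, the 27 that were not called had a median log2 change of 0.16, 22 of them above 0, and a camera p of 0.032, which fits a shift of the group. With an estimated correlation that p was 0.074, and the list includes clock regulators such as PRR37 that only share a domain. The shift remains a hypothesis.

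For suberin synthesis the same hypothesis, that the whole group may have shifted, stays open. The 16 members that were not called had 8 log2 changes above 0 and 8 below it, with a camera p of 0.40, or 0.57 with an estimated correlation. A test that leaves out the called members cannot exclude a shift, although it was set down as one that would. Of the 19 members tested, 13 also stood in a list fixed beforehand. The called members were unigenes of the feruloyl transferase, MYB39 and 3-ketoacyl-CoA synthase 20. Other unigenes of MYB39, not called, had log2 changes of -3.64 and 0.86 in the wax apple fit. Those of the feruloyl transferase, also not called, had log2 changes of -2.09 and -0.68 in that fit.

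A candidate explanation for the insect transcripts is larvae rather than adults in the fruit. Unigenes of larval markers (11) summed to 57.6, 1694 and 41.2 CPM in melatonin libraries 1, 2 and 3, and those of adult and egg markers (3) to 0.466, 9.04 and 2.86 CPM. The ratio of the means was 145, which fits larvae, and 29.7 without melatonin library 2, but it sets different numbers of different genes against each other and was lowest in melatonin library 3. The term oogenesis was enriched among higher unigenes (5 of 12 members). Insect RNA of any stage could enrich such a term in a background of mostly plant unigenes, so it cannot tell adults from larvae. Adults stay possible as well. Of the larval unigenes 6 were tested and edgeR called 0.

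The 10 ways to split the libraries 3 against 3 are too few for a share under 0.05, and the smallest share possible is 0.1. A count as large as in the real grouping came in 1 of 10 splits for unigenes (597, highest other 0), for the wax apple fit (6, highest other 0), for terms (71, highest other 0) and for wax apple terms (8, highest other 0). With 0 unigenes called in the other splits, both term counts had to be 0 there. For lists a count as large as in the real grouping came in 10 of 10 splits (2, highest other 10). For lists among wax apple unigenes it came in 8 of 10 (5, highest other 13). Splits that call many more lists than the real one may point to a structure of the samples or to the preset correlation between genes. Neither was tested, and 0 lists passed in the real grouping with an estimated correlation. Among wax apple unigenes a camera p as small came in 1 of 10 splits for phenylpropanoid and lignin enzymes, 2 for photosynthesis, 3 for class III peroxidases and for mitochondrial respiration, and 6 for disease resistance receptors. Over all unigenes it came in 3 of 10 splits for phenylpropanoid and lignin enzymes and in 3 for ribosomal proteins.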
